A study of Homo sapiens with 12 samples.

How the data were processed

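Human SH-SY5Y neuroblastoma cells were profiled on Affymetrix Clariom S Human arrays, a short-oligonucleotide platform that gives 1 value per gene-level probe set. Each of the 12 arrays was hybridised with RNA of 1 sample, and the labels place 3 arrays in each of 4 groups named Ctrl, MPP, Pselt and Pselt+MPP. Replicate numbers used here only follow the order of the samples within a group and pair nothing. Per the labels' protocols, cells received the neurotoxin MPP+ for 36 h at either 500 µM or 1 mM, and the peptide PSELT at 10 µM, which for the arrays was applied for only 6 h. The dose of MPP+ behind the arrays and the timing of the 6 h relative to the toxin are not given in the sources used here. Labelling started from total RNA, per the labels' protocols.

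The deposited values are log2 signals that the authors produced with the RMA method in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background of each array, brings the arrays to a common distribution and summarises the probes of each probe set. The version and settings are not given in the sources used here. The unit was read from RMA's usual output and from the values, whose array medians lay between 6.48 and 6.61 over the probe sets of genes. In all, 123 of those probe sets had a value above 16, the log2 of a 16-bit scanner reading of 65535, on some array. A transform that stretched the signal before RMA is possible and is not stated, so a fold change here is a fold on the deposited scale and the largest folds depend on that scale. The table has no detection calls, and no signal over background was used here.

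Of 24351 entries in the deposited table, 2903 were control features and were left out. The remaining 21448 probe sets entered every test. Gene symbols came from a table pairing the platform's probe sets with gene annotation, updated through the gene number against a RefSeq gene table. This gave 17709 probe sets with 1 symbol, 0 with several and 3739 with none, for 17687 genes. Unnamed probe sets were tested and counted, and are given by identifier where they are described. Coordinates are not reported. All 12 columns of sample values were used, and 0 were left out.

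Differential expression was tested with limma 3.58.1 in R 4.3.3. A linear model with 4 group means was fitted to each probe set over all 12 arrays (lmFit), so that the groups shared 1 estimate of the spread, with 8 residual degrees of freedom and 9.56 prior degrees of freedom from eBayes. Contrasts gave the MPP effect with and without Pselt, the Pselt effect with and without MPP, the combined treatment against Ctrl, and the interaction, which is the Pselt effect in MPP-treated cells minus that in untreated cells. Limma's moderated test was two-sided, p-values were adjusted over all 21448 probe sets of a contrast by the Benjamini-Hochberg method, and an adjusted p below 0.05 was taken as the threshold. An F test over the group means asked whether any groups differed. No term for pairing or batch was used, because the labels give neither.

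Gene lists from textbook knowledge, 48 in number, were written down in advance. For each gene the probe set with the highest mean signal was used. Of these lists, 47 had at least 5 measured members and were tested with camera, which asks whether the genes of a list are shifted relative to all other genes, with the preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 47 lists. One list, of mitochondrially encoded genes, had 0 named members and was not tested. Camera was repeated with the correlation estimated for each list, and the p-value from that run is given beside the lists described whose call was lost with it. Members of a list were counted at limma's adjusted p over all probe sets and again adjusted over the list alone. The adjustment over the list alone does not cover the number of lists or comparisons, and it was not repeated with arrays left out.

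Genes named in the text follow a fixed rule. For the MPP effect without Pselt and for both Pselt effects they are up to 12 genes with the largest rise and up to 12 with the largest fall among those that passed the threshold, carried 1 symbol, had a mean signal above the median of 6.54, and had all 3 arrays of a group on one side of all 3 of the other. For the other pairwise contrasts the limit was 5 each way, and for the interaction 5 each way without the condition on single arrays. Where no gene passed, the 5 with the smallest p are given and said not to pass. These were taken only from genes with 1 symbol and a mean signal above that median. Up to 4 members with the smallest p are named per list described, together with a fixed set of genes of the catecholamine and stress pathways, of which 1 is not reported here. A few symbol classes, such as unnamed loci and small RNAs, were counted and not named. Probe sets with M in the chromosome field of their identifier, and the haemoglobin genes HBA1 and HBB, were singled out after their values were seen.

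Relations between 2 contrasts were described by Pearson and Spearman correlations across probe sets, which are not independent replicates. Contrasts that share arrays have correlated errors, so unchanged groups were simulated 100 times with the measured spread, and the observed covariance was set beside the simulated one. Probe sets were drawn independently of each other, so the simulations leave out that genes vary together. The number of genes moved back by Pselt, meaning called in the MPP effect and called in the opposite direction when Pselt was added to MPP, was compared with simulations. In these, MPP and Pselt+MPP were both given the average of their 2 group means. A first such simulation took the measured means as the truth and made 760 calls on average where the data made 53, so a second, with effects only in the called probe sets, was added after its result was seen.

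The fitting and list scripts were tested on simulated data for the MPP effect without Pselt, with 21448 probe sets, 5 draws and 200 changed probe sets in each. Limma called 12.2% of those changed 1.5-fold (41 of 335), 69.9% of those changed 2-fold (234 of 335) and 100% of those changed 4-fold (330 of 330), with 33 false calls beside 605 true ones. A list of 40 genes shifted by 0.3 was called in 5 of 5 draws, and an unshifted list in 0 of 5. The list check held only these lists, so it does not cover the adjustment over all tested lists. Nor does it cover lists whose genes vary together, as those of real lists did. It therefore cannot vouch for the list calls in the data, most of which were lost with an estimated correlation.

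The comparisons, the gene lists, the rule for named genes and the following alternatives were fixed before the data were examined: a mean-dependent prior variance, robust eBayes, array weights, removal of probe sets below the median signal, removal of unnamed probe sets, cyclic loess or median centring on top of the deposited values, a minimum fold of 1.5, an unadjusted p below 0.05 with a 2-fold change, the 2 compared groups alone, and leaving out each array in turn. Lists were also tested with camera on ranks, with the mean of a gene's probe sets, and with fry, whose directional p tests whether the genes of a list move one way on balance and whose mixed p tests whether they change in either direction. Leaving out the 2 arrays farthest from their group mean on the first principal components, and repeating the comparison of MPP effects on other sets of probe sets, were added after seeing the data, as was the removal of Pselt+MPP replicate 3 for the haemoglobin genes.

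The number of arrays limits the precision. The median standard error of a pairwise log2 difference was 0.21, which gives a 95% interval of about 0.44 on either side, and that of the interaction was 0.3. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.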

Results

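Gene expression was measured in SH-SY5Y cells, a human neuroblastoma line with noradrenergic features that is widely used as a model of catecholaminergic neurons. Cells were left untreated (Ctrl), exposed to MPP+, a toxin that is taken up by catecholamine transporters and inhibits complex I of the respiratory chain (MPP), given PSELT, a peptide that the series title describes as a cell-penetrant mimetic of the selenoprotein SELENOT (Pselt), or given both (Pselt+MPP). Each of the 4 groups had 3 arrays, 12 in all, and this number limits the precision. Values are the authors' log2 RMA signals. The arrays were alike, with correlations between 0.981 and 0.996 over 21448 probe sets and 0 identical pairs. Pselt replicate 3 and MPP replicate 3 stood farthest from their groups on the first 2 principal components, which held 23.8% and 18.9% of the variance. The labels do not say that the arrays of a group are separate cultures, so p-values measure only the spread between these samples.

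The first comparison asked how MPP+ changed expression in the absence of the peptide. The strongest rise of a named gene was that of SLC7A11, the cystine transporter subunit of system xc-, whose mean signal went from 6.96 ± 0.23 in Ctrl to 10.89 ± 0.29 in MPP (SD, n = 3 each), a 15.3-fold difference (log2 change 3.93, SE 0.2, adjusted p = 2e-09, limma). SLC7A5, a transporter of large neutral amino acids, rose 8.13-fold (log2 change 3.02, SE 0.36, adjusted p = 0.00022). CHAC1, an enzyme that degrades glutathione, rose 7.13-fold (log2 change 2.83, SE 0.22, adjusted p = 6.4e-07), and ASNS, which makes asparagine, rose 3.81-fold (log2 change 1.93, SE 0.2, adjusted p = 4.1e-05). The serine synthesis enzymes PHGDH and PSAT1 rose 3.44-fold and 3.15-fold, and MTHFD2, an enzyme of mitochondrial folate metabolism, rose 2.95-fold (adjusted p = 0.0051, 9.7e-05 and 0.00018). The glycine transporter SLC6A9 rose 3.52-fold, the neutral amino acid transporter SLC1A4 3.05-fold, the mitochondrial phosphoenolpyruvate carboxykinase PCK2 3.43-fold and the seryl-tRNA synthetase SARS1 3.03-fold, with adjusted p between 0.00038 and 0.0028. DDIT4, an inhibitor of mTORC1 signalling, rose 2.91-fold (adjusted p = 0.011), and its call was lost without MPP replicate 2 (adjusted p = 0.086) and with the 2 groups fitted alone (0.079). For each of these 12 genes all 3 MPP arrays lay above all 3 Ctrl arrays. SRGAP1 was the only gene named by the rule that fell, with a log2 change of -1.19 (SE 0.22, adjusted p = 0.024), lower on all 3 arrays. Its call was lost without Ctrl replicate 1 (adjusted p = 0.14), Ctrl replicate 2 (0.13), MPP replicate 1 (0.066) or MPP replicate 2 (0.19), and with the 2 groups alone (0.082).

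In all, 53 of 21448 probe sets passed the threshold for MPP against Ctrl, 45 higher and 8 lower, and 42 of them carried a gene name (41 higher, 1 lower). At an unadjusted p below 0.05 there were 1993, against 1072 expected by chance. Of the named ones, 35 changed beyond 2-fold. Without MPP replicate 2 the count was 35.

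**Figure D1:**
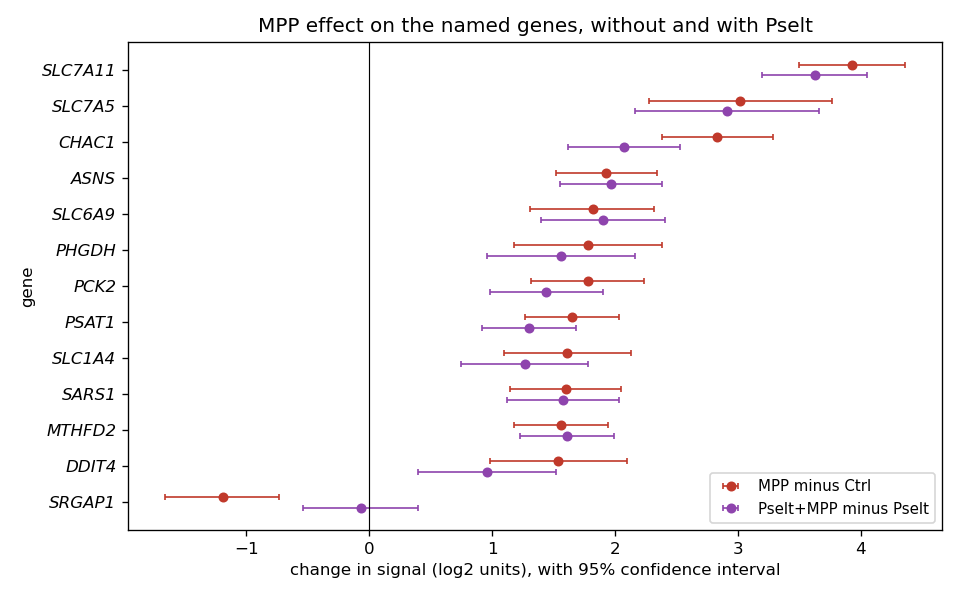
Log2 change of the 13 genes named for the MPP effect, with MPP minus Ctrl in red and Pselt+MPP minus Pselt in purple. Points are limma estimates from 3 arrays per group and bars are 95% confidence intervals; SLC7A11 lies at 3.93 and 3.63, while SRGAP1 lies at -1.19 and -0.07.

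Genes of the ATF4 and amino acid stress response, a programme of amino acid synthesis, transport and tRNA charging, rose together with MPP+. Of its 47 measured members 22 rose, 0 fell and 25 did not pass over all genes, and 38 rose when adjusted over the list alone. The median log2 change was 1.09, 45 members lay above 0, and camera gave an adjusted p of 2.5e-64. The call held with an estimated correlation (adjusted p = 0.00013). DDIT3, the stress-induced transcription factor CHOP, rose 3.57-fold (log2 change 1.83, SE 0.23, adjusted p = 0.00048). ATF3, another stress-induced factor, had a log2 change of 1.09 (SE 0.24) that did not pass (adjusted p = 0.071), although it passed without Ctrl replicate 1 or Pselt replicate 3 (0.048 in both) and with array weights (0.04). The ER chaperone HSPA5 had a log2 change of -0.36 (SE 0.17), the cell cycle inhibitor CDKN1A of 0.28 (SE 0.23) and EZH2, the catalytic subunit of Polycomb complex PRC2, of -0.57 (SE 0.2), and none of these passed (adjusted p = 0.55, 0.76 and 0.4). The list of ER chaperones and the unfolded protein response, which holds HSPA5, lay slightly higher as a group (31 members, median 0.13, camera adjusted p = 0.047). That call was lost with an estimated correlation (adjusted p = 0.45), with cyclic loess (0.051) and in 6 of 12 leave-outs of 1 array, where p ranged from 0.021 to 0.23. The arrays whose removal ended it were Ctrl replicates 1 and 2, MPP replicates 2 and 3, Pselt replicate 1 and Pselt+MPP replicate 1. None of its members passed over all genes and 1 rose adjusted over the list alone, HERPUD1, a factor of ER-associated degradation (log2 change 0.86, SE 0.19).

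Genes that act in cell division lay lower with MPP+. The list of G1/S and DNA replication genes had a median log2 change of -0.31, with 32 of 35 members below 0 (camera adjusted p = 7.9e-09), and the G2/M and mitosis list also had a median of -0.31, with 34 of 39 below 0 (camera adjusted p = 1e-07). With an estimated correlation neither passed (adjusted p = 0.33 and 0.45). Of both lists 0 members passed over all genes or adjusted over the list alone. The members with the smallest p were the replication checkpoint adaptor CLSPN (log2 change -0.63, SE 0.2), the maintenance methylation factor UHRF1 (-0.53, SE 0.18), the cytokinesis scaffold ANLN (-0.51, SE 0.18) and the cyclin CCNA2 (-0.54, SE 0.2). Mean signal of the G1/S list was 11.04 ± 0.04 in Ctrl and 10.73 ± 0.09 in MPP, and that of the G2/M list 11.79 ± 0.16 and 11.51 ± 0.2 (SD, n = 3). For G2/M the groups overlapped, with MPP replicate 3 at 11.74, above Ctrl replicates 2 and 3 (11.71 and 11.67) and level with Pselt+MPP (11.72 ± 0.07). Replication-dependent histone genes, which are transcribed in S phase, had a median of -0.24 over 32 members (camera adjusted p = 0.0023). They moved together from array to array, with an estimated correlation of 0.78, and the call was lost with it (adjusted p = 0.9) and without Ctrl replicate 3 (adjusted p = 0.8). Lysosome and autophagy genes had a median of 0.22 over 33 members (camera adjusted p = 0.0096), with 0 members passing over all genes or adjusted over the list alone. This call was lost with an estimated correlation (adjusted p = 0.45) and without MPP replicate 3 (adjusted p = 0.2). Examples were the autophagy receptor SQSTM1 (log2 change 0.73, SE 0.22) and the proton pump accessory subunit ATP6AP1 (0.79, SE 0.3). In total 6 of 47 lists passed for this comparison, and 1 passed with an estimated correlation, the ATF4 list. Without Ctrl replicate 3 the count was 11.

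The catecholaminergic identity of the cells showed no change that passed. The list of catecholamine synthesis, transport and breakdown genes had a camera adjusted p of 0.97 over 19 members, where the test and the mean (0.05) pointed up and the median (-0.05) down. TH, the rate-limiting enzyme of dopamine synthesis, had a mean log2 signal of 5.22 ± 0.49 in Ctrl and 4.83 ± 0.08 in MPP, and DBH, which turns dopamine into noradrenaline, 13.61 ± 0.25 and 13.98 ± 0.31 (SD, n = 3). The noradrenaline transporter SLC6A2 stood at 13.41 and 13.35, and the dopamine transporter SLC6A3, a route of MPP+ uptake, at 5.54 and 5.78. The vesicular transporters SLC18A1 (9.03 and 9.39) and SLC18A2 (6.65 and 6.6), the monoamine oxidase MAOA (8.07 and 8.37) and SELENOT itself (13 and 13.12) did not pass either. HMOX1, an oxidative stress gene, had means of 3.77 and 3.7. The signals of HMOX1, TH and SLC6A3 lay below the median of 6.54, and without detection calls a lack of change there says little. Nuclear-encoded subunits of complex I, the target of MPP+, had a median log2 change of 0.13 over 32 members (camera adjusted p = 0.076). The 24 measured selenoproteins had a camera adjusted p of 0.33.

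Of the 8 probe sets that fell, 6 were unnamed and carried M in the chromosome field of their identifier. In 17692 of 17699 named probe sets this field matched the gene's chromosome. These probe sets were singled out after their values were seen. Among the 10 with M in that field 6 fell, 1 rose and 3 did not pass. TC0M00006443.hg.1 had the lowest change of any probe set, from 16.8 ± 0.47 in Ctrl to 9.93 ± 0.31 in MPP (SD, n = 3), 117-fold lower (log2 change -6.87, SE 0.3, adjusted p = 2.7e-10). TC0M00006442.hg.1 was 48.9-fold lower (log2 change -5.61, SE 0.28, adjusted p = 1.3e-09). TC0M00006454.hg.1 went the other way, from 12.67 ± 0.84 to 15.2 ± 0.2, a 5.77-fold rise (log2 change 2.53, SE 0.34, adjusted p = 9e-04). For these 3 probe sets the calls held in 12 of 12 leave-outs. The call of 1 other, TC0M00006439.hg.1 (log2 change -1.18, SE 0.23, adjusted p = 0.03), held in 4 of 12, with p up to 0.19, and was lost without Ctrl replicate 1 or 3, any MPP array or any Pselt+MPP array. Several of these signals exceeded 16 in Ctrl, above the log2 of a 16-bit reading, so their folds depend on how the signal was scaled.

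**Figure D2:**
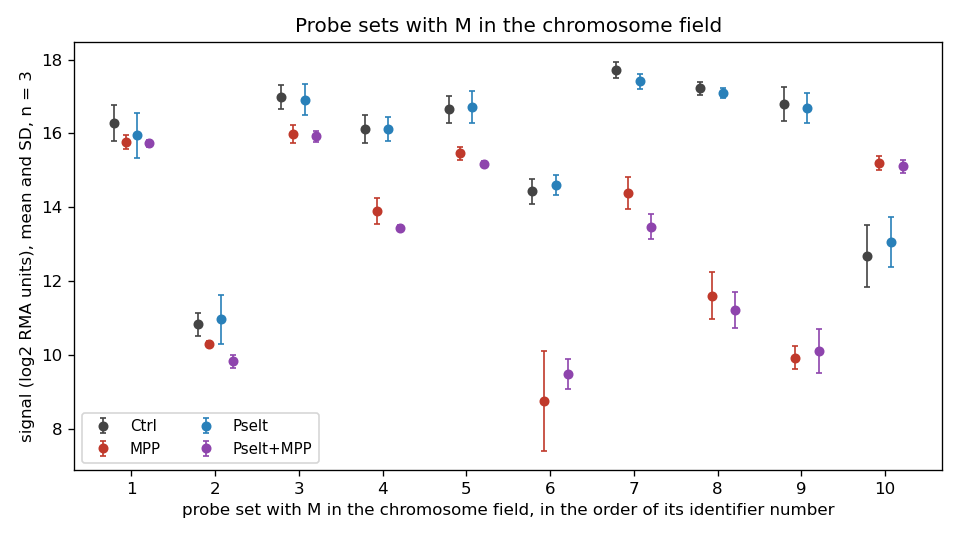
Mean log2 RMA signal with SD (n = 3 arrays) of the 10 probe sets with M in the chromosome field, ordered by identifier number, for Ctrl (grey), MPP (red), Pselt (blue) and Pselt+MPP (purple). At position 9 the signal was 16.8 in Ctrl and 9.93 in MPP, and at position 10 it was 12.67 and 15.2, while Ctrl and Pselt differed by 0.39 or less throughout.

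The next comparison asked what the peptide did in cells without the toxin. Limma called 0 of 21448 probe sets for Pselt against Ctrl, with a smallest adjusted p of 0.58. At an unadjusted p below 0.05 there were 1523, against 1072 expected, and the mean-dependent prior, robust and array-weighted fits also called 0. Without MPP replicate 3, 1 passed. Under the naming rule, none of the genes with the smallest p passed. They included the mitotic spindle organiser MZT1 (log2 change 0.98, SE 0.2), the caspase CASP6 (0.99, SE 0.21) and the cell adhesion molecule NLGN4X (0.82, SE 0.18). The others were the mitochondrial co-chaperone DNAJA3 (-0.79, SE 0.18) and the calcium-binding protein GCA (0.84, SE 0.19). Each had an adjusted p of 0.58. SELENOT had a log2 difference of 0.24 (SE 0.18, adjusted p = 0.77). The probe sets with M in the chromosome field lay between -0.33 and 0.39 and 0 of 10 passed. The ATF4 list had a median of 0.02 over 47 members, while camera's test pointed down (adjusted p = 0.99), with 0 members passing either way of adjusting. Adjusted over the list alone, CASP6 passed among the apoptosis regulators (adjusted p = 0.0054) and CDT1, a replication licensing factor, among the G1/S genes (log2 change -1.03, SE 0.24, adjusted p = 0.017). These lists as a whole did not pass (camera adjusted p = 0.66 and 0.8), and for the G1/S list the test and the mean (-0.03) pointed down and the median (0.03) up. Neither CASP6 nor CDT1 passed over all genes, and an adjustment over a single list does not cover the other lists.

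Histone genes were the only one of 47 lists past the threshold for Pselt against Ctrl, with a median log2 change of -0.23 and 29 of 32 members below 0 (camera adjusted p = 0.0011). With an estimated correlation the adjusted p was 0.99. Of its members 0 passed over all genes or adjusted over the list alone, with H4C4 at -0.61 (SE 0.28) and H2BC14 at -0.46 (SE 0.22). The call was lost without Ctrl replicate 3 (adjusted p = 0.73), and without Pselt replicate 3 the direction turned (adjusted p = 0.46). Without Ctrl replicate 1 the number of lists was 2. Leaving out Pselt replicate 3 also brought 12 lists past the threshold, all higher in Pselt, among them complex I subunits with a median of 0.21 (camera adjusted p = 0.00085). With an estimated correlation 0 of these passed, with a smallest adjusted p of 0.35.

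Whether the peptide changed expression in toxin-treated cells was addressed by Pselt+MPP against MPP. Limma called 0 of 21448 probe sets, with a smallest adjusted p of 0.57. At an unadjusted p below 0.05 there were 1378, and the mean-dependent prior, robust and array-weighted fits called 0. None of the genes with the smallest p under the naming rule passed. They were the stress-responsive kinase PLK2 (log2 change 0.98, SE 0.21, adjusted p = 0.57), SHISA5 (0.95, SE 0.22), the small GTPase RAB30 (1.04, SE 0.24), the thioredoxin-domain protein TXNDC9 (0.87, SE 0.21) and the haemoglobin gene HBA2 (2.59, SE 0.59), the last 4 with an adjusted p of 0.74. HBA2 is nearly identical to HBA1, so the 2 cannot be told apart with certainty on the array. Its signal was 10.9 on Pselt+MPP replicate 3 against 5.6 to 7.8 on the other arrays. The list of 12 blood cell markers did not pass (camera adjusted p = 0.88; mean 0.25, median -0.14), but 2 members rose adjusted over the list alone, HBA1 (2.56, SE 0.62) and HBB (1.64, SE 0.41). Without Pselt+MPP replicate 3 the differences were 1.52 for HBA2, 1.46 for HBA1 and 0.93 for HBB. SELENOT differed by 0.08 (SE 0.18), TH by 0.54 (SE 0.23), and EZH2 by 0.49 (SE 0.2), with adjusted p of 0.95, 0.77 and 0.77.

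Genes of cell division lay slightly higher, as a group, in Pselt+MPP than in MPP, in a comparison that shares the MPP arrays with that of MPP against Ctrl. The G2/M list had a median log2 change of 0.23 with 35 of 39 members above 0 (camera adjusted p = 0.00091), and the G1/S list 0.13 with 27 of 35 above 0 (camera adjusted p = 0.029). Neither call held with an estimated correlation (adjusted p = 0.65 for both) or with cyclic loess on top of the deposited values (0.12 and 0.52). The G1/S call was also lost without MPP replicate 1 (adjusted p = 0.22), MPP replicate 3 (0.091) or Pselt+MPP replicate 2 (0.16), and among probe sets above the median signal (0.34), with a range of 0.008 to 0.22 over the leave-outs. Of both lists 0 members passed over all genes or adjusted over the list alone. Examples were the mitotic checkpoint kinase BUB1 (0.49, SE 0.21), the cyclin CCNB1 (0.42, SE 0.19), the replicative helicase subunit MCM6 (0.51, SE 0.19) and the transcription factor E2F8 (0.61, SE 0.27). Histone genes went the other way, with a median of -0.19 over 32 members (camera adjusted p = 0.001). That call was lost with an estimated correlation (adjusted p = 0.73), without MPP replicate 3 (0.064) and without Pselt+MPP replicate 2 (0.16), and 0 members passed either way of adjusting, with H4C1 at -1 (SE 0.49) and H3C7 at -0.49 (SE 0.24). In all, 3 lists passed for this comparison and 0 with an estimated correlation. The count was 1 without MPP replicate 3 or Pselt+MPP replicate 2, 5 without Pselt+MPP replicate 1 and 6 among probe sets above the median signal. The ATF4 list did not pass (median -0.07, 26 of 47 members below 0, camera adjusted p = 0.15). Its member with the smallest p was CHAC1, with a log2 difference of -0.74 (SE 0.22) that did not pass over all genes (adjusted p = 0.77) or adjusted over the list alone (0.14).

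**Figure D3:**
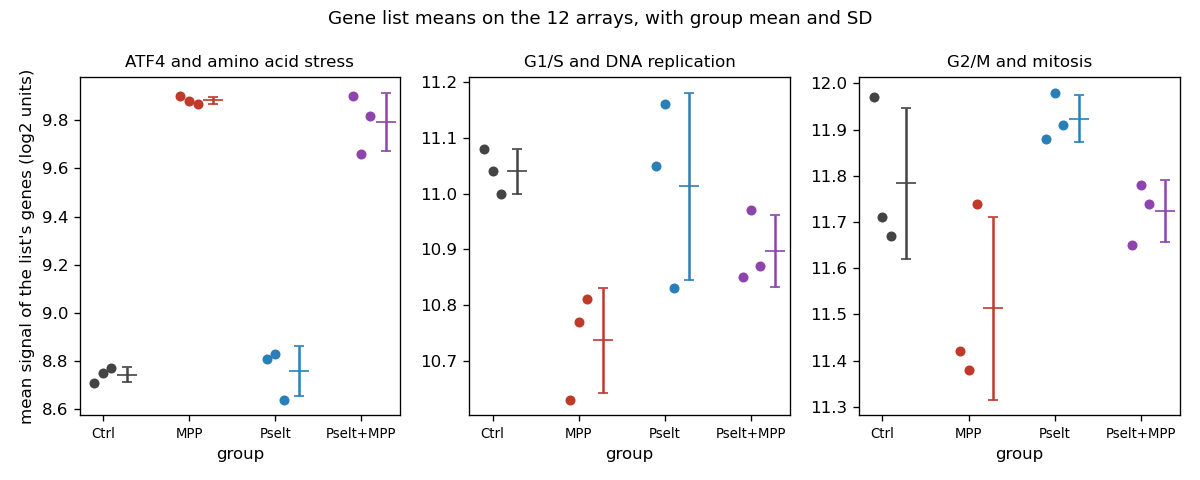
Mean log2 signal of the genes of 3 lists on each of the 12 arrays (points), by group, with the group mean and SD (n = 3) beside them. The ATF4 list stands at 8.74 in Ctrl, 9.88 in MPP, 8.76 in Pselt and 9.79 in Pselt+MPP, and the G1/S list at 11.04, 10.73, 11.02 and 10.9.

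The number of MPP-responsive probe sets moved back by the peptide was 0 of 53, a count fixed by the 0 limma calls for Pselt+MPP against MPP, and simulations without any Pselt effect gave 0.02. The comparisons MPP against Ctrl and Pselt+MPP against MPP share the MPP arrays, which alone pushes their changes in opposite directions. Of the 53 called probe sets 37 (69.8%) had the opposite sign in Pselt+MPP against MPP. Simulations without any Pselt effect gave 56% on average (35.7 to 72.7), or 76.7% (73.4 to 79.7) when the measured means were taken as true. Over all probe sets the covariance of the 2 changes was -0.0252, against -0.0245 in simulated unchanged groups (-0.0253 to -0.0235). The groups of 3 arrays cannot be split into parts of 2 arrays. The MPP and Pselt calls shared 0 probe sets, with 0 expected, since 0 were called for Pselt. The covariance of these 2 changes, which share the Ctrl arrays, was 0.0272, against 0.0245 in simulated unchanged groups (0.0238 to 0.0254). The correlation of these 2 changes was 0.357, below the simulated 0.5 (0.489 to 0.516). Simulated probe sets varied independently, while real genes such as the histones moved together. These simulated ranges are therefore too narrow, and no conclusion is drawn from a value outside them.

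Expression under both treatments was then compared with untreated cells. SLC7A11 rose 12.8-fold (log2 change 3.68, SE 0.2, adjusted p = 4.5e-09, limma), SLC7A5 7.55-fold (adjusted p = 0.00035), CHAC1 4.26-fold (5.1e-05), ASNS 3.97-fold (2.9e-05) and SARS1 3.5-fold (0.00028), with all 3 Pselt+MPP arrays above all 3 Ctrl arrays for each. DDIT3 rose with a log2 change of 1.58 (adjusted p = 0.0021) and ATF3 with 1.3 (adjusted p = 0.02). The ATF3 call was lost without Ctrl replicate 2 (adjusted p = 0.084), Ctrl replicate 3 (0.12), Pselt+MPP replicate 1 (0.13) or Pselt+MPP replicate 3 (0.11). In all, 61 of 21448 probe sets passed, 52 higher and 9 lower, and 51 of them carried a gene name (49 higher, 2 lower). There were 2631 at an unadjusted p below 0.05. The count fell to 32 without Ctrl replicate 2, 38 without Ctrl replicate 3, 35 without Pselt+MPP replicate 1 and 33 without Pselt+MPP replicate 3, and with array weights it was 146. Of the probe sets with M in the chromosome field 6 fell and 1 rose, and TC0M00006443.hg.1 was 103-fold lower.

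Of the 47 lists 13 passed for Pselt+MPP against Ctrl, 11 higher and 2 lower, and 1 passed with an estimated correlation. The count was 5 without Ctrl replicate 1, 6 without Pselt+MPP replicate 1, and 7 with cyclic loess or among probe sets above the median signal. The list that passed with an estimated correlation was the ATF4 list, with a median log2 change of 1.01 (camera adjusted p = 3e-46, 0.00044 with an estimated correlation). Of its 47 members 24 rose, 0 fell and 23 did not pass over all genes, and 37 rose adjusted over the list alone. For the other 12 lists the adjusted p with an estimated correlation was between 0.079 and 0.77. Among them, p53 target genes had a median of 0.37 over 25 members (camera adjusted p = 0.0025, adjusted p = 0.079 with an estimated correlation). Of these 0 passed over all genes and 2 rose adjusted over the list alone, the death receptor TNFRSF10B (log2 change 1.01, SE 0.21) and CCNG1 (0.76, SE 0.18), both known p53 targets. The p53 list shares SESN2 and GDF15 with the ATF4 list and was not tested without them. Lysosome and autophagy genes had a median of 0.38 over 33 members (camera adjusted p = 1.2e-05, adjusted p = 0.092 with an estimated correlation). Again 0 passed over all genes and 2 rose adjusted over the list alone, SQSTM1 (0.79, SE 0.22) and the protease CTSD (0.8, SE 0.23). Histone genes had a median of -0.52 with 31 of 32 members below 0 (camera adjusted p = 4.4e-10, adjusted p = 0.51 with an estimated correlation), and 0 passed either way of adjusting, with H4C4 at -1.01 (SE 0.28). The other lower list was that of the G1/S and DNA replication genes, with a median of -0.11 and 28 of 35 members below 0 (camera adjusted p = 0.0085, adjusted p = 0.47 with an estimated correlation). Of these 0 passed either way of adjusting, with GINS2, a subunit of the replicative helicase, at -0.67 (SE 0.21), and the call was lost without Ctrl replicate 1 or Pselt+MPP replicate 1, where p reached 0.056. Among apoptosis regulators, CASP6 rose 2.19-fold (log2 change 1.13, SE 0.21, adjusted p = 0.024). It was the only one of 27 members past the threshold over all genes and adjusted over the list alone (camera adjusted p = 0.021, adjusted p = 0.22 with an estimated correlation). The CASP6 call was lost with cyclic loess (adjusted p = 0.078) and without Ctrl replicate 2 (0.14), Ctrl replicate 3 (0.072), or Pselt+MPP replicate 1 (0.17), 2 (0.076) or 3 (0.074). The call of the list was lost without Ctrl replicate 1 or Pselt+MPP replicate 1, where p reached 0.085, and with cyclic loess (0.13).

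The effect of MPP+ was measured again in the presence of the peptide, as Pselt+MPP against Pselt. SLC7A11 rose 12.3-fold (log2 change 3.63, SE 0.2, adjusted p = 7.8e-09, limma), SLC7A5 7.52-fold (adjusted p = 3e-04), CHAC1 4.21-fold (5.9e-05), ASNS 3.91-fold (3.5e-05) and SLC6A9 3.74-fold (0.00043), higher on all 3 arrays. Of the other genes named above, DDIT4 (log2 change 0.96, adjusted p = 0.41) and SRGAP1 (-0.07, adjusted p = 0.98) did not pass here. In all, 41 of 21448 probe sets passed, 33 higher and 8 lower, with 32 named (31 higher, 1 lower) and 1368 at an unadjusted p below 0.05. The count was 27 without Pselt replicate 1, 27 without Pselt replicate 3, 24 without Pselt+MPP replicate 1 and 22 without Pselt+MPP replicate 3. It was 25 with the 2 groups alone and 85 with array weights.

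Among the lists for Pselt+MPP against Pselt, 8 passed and 2 held with an estimated correlation, and the count was 13 without Pselt replicate 3 and 12 without Pselt replicate 2. The ATF4 list had a median log2 change of 0.92 (camera adjusted p = 1.3e-66, 0.00011 with an estimated correlation), with 18 of 47 members rising, 0 falling and 29 not passing over all genes, and 35 rising adjusted over the list alone. The p53 targets had a median of 0.15 with 24 of 25 members above 0 (camera adjusted p = 8.4e-05, 0.025 with an estimated correlation). None of them passed over all genes, and 2 rose adjusted over the list alone, CDKN1A (log2 change 0.99, SE 0.23) and TNFRSF10B (0.89, SE 0.21). Among probe sets above the median signal the p53 call was lost (adjusted p = 0.091), while it held in 12 of 12 leave-outs (4.5e-05 to 0.0027). The list was not tested without SESN2 and GDF15, which also belong to the ATF4 list. NRF2 target genes, which serve antioxidant defence, had a median of 0.07 (camera adjusted p = 3e-04, adjusted p = 0.13 with an estimated correlation). Of 25 members 2 rose over all genes and 3 adjusted over the list alone, with SLC7A11 and the quinone reductase NQO1 (log2 change 1.23, SE 0.21, adjusted p = 0.014) passing both ways. SLC7A11 also belongs to the ATF4 list, and the NRF2 call was lost without Pselt+MPP replicate 1 (adjusted p = 0.05) and with camera on ranks (0.061). HERPUD1 rose as well (log2 change 1.06, SE 0.19, adjusted p = 0.026). Both gene calls were lost without Pselt replicate 1, Pselt replicate 3, Pselt+MPP replicate 1 or Pselt+MPP replicate 3, where p reached 0.15 for NQO1 and 0.23 for HERPUD1, and with the 2 groups alone (0.057 and 0.1). The NQO1 call was also lost without Pselt replicate 2 (adjusted p = 0.062). The division lists lay lower again, with a median of -0.16 for G1/S (camera adjusted p = 0.011) and -0.2 for G2/M (4.8e-05), adjusted p = 0.7 for both with an estimated correlation and 0 members passing either way of adjusting. The G1/S call was lost without Pselt replicate 1, Pselt replicate 2 or Pselt+MPP replicate 1, where p reached 0.28. Histone genes had a median of -0.22 with 29 of 32 members below 0 (camera adjusted p = 9e-04, adjusted p = 0.82 with an estimated correlation), and 0 passed either way of adjusting, with H2BC4 at -0.58 (SE 0.22). That call was lost without Pselt replicate 1, Pselt replicate 2 or Pselt+MPP replicate 2, where p reached 0.44. Lysosome and autophagy genes had a median of 0.22 with 30 of 33 above 0 (camera adjusted p = 8.4e-05, adjusted p = 0.11 with an estimated correlation), a call that held in 12 of 12 leave-outs. Of these 0 passed over all genes and 1 rose adjusted over the list alone, SQSTM1 (0.85, SE 0.22).

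The MPP effects without and with the peptide were then set side by side. All 53 probe sets called for MPP against Ctrl had the same sign in Pselt+MPP against Pselt, and 33 were called in both (27 higher, 6 lower), against 0.069 and 0.003 expected for independent lists. These 2 effects share no arrays. Both were tested with the same estimate of the spread of each probe set, so the lists are not fully independent. The expected numbers leave this out. Across the 53, which are not independent replicates, the Pearson correlation was 0.979 and the Spearman correlation 0.887, and without the M-field probe sets the Pearson correlation was 0.852 over 46. The change with Pselt was the smaller one in 40 of 53, with a median ratio of 0.81. Selecting instead the 41 probe sets called with Pselt, the change without Pselt was the smaller one in 21 of 41, with a median ratio of 0.98. Those 53 were chosen for their MPP change. Over all 21448 probe sets the MPP effects had a Pearson correlation of 0.418 and a Spearman correlation of 0.306, with the same sign in 12905, and the Pselt effects without and with MPP had 0.304 and 0.301.

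**Figure D4:**
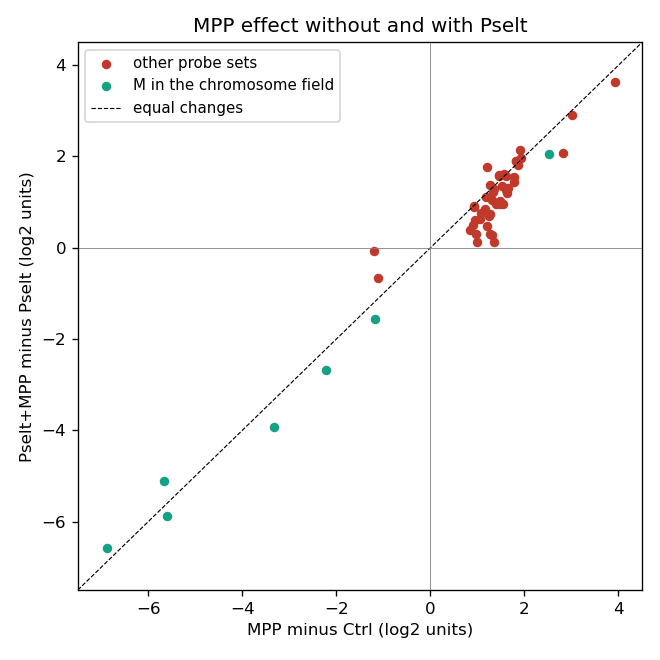
Log2 change with MPP+ in cells without Pselt (x axis, MPP minus Ctrl) and with Pselt (y axis, Pselt+MPP minus Pselt) for the 53 probe sets called without Pselt, with probe sets carrying M in the chromosome field in green and the others in red. The dashed line marks equal changes; the points run from -6.87 on the x axis to 3.93 and all 53 have the same sign on both axes.

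The interaction tested directly whether the peptide altered the MPP effect. Limma called 0 of 21448 probe sets, with a smallest adjusted p of 1, and there were 703 at an unadjusted p below 0.05, fewer than the 1072 expected. The mean-dependent prior, robust and array-weighted fits called 0. Again none of the genes with the smallest p under the naming rule passed. They were TMEM234 (interaction -1.05, SE 0.28), TMEM51 (0.91, SE 0.25), SRGAP1 (1.13, SE 0.31), CSRP1 (1.03, SE 0.29) and RNF175 (-1.01, SE 0.29). For the interaction 1 of 47 lists passed, the G1/S and DNA replication genes, with a median of 0.15 and 27 of 35 members above 0 (camera adjusted p = 0.043). The call was lost with an estimated correlation (adjusted p = 0.96) and with cyclic loess (0.17), and 0 members passed over all genes or adjusted over the list alone, with CDT1 at 0.89 (SE 0.34). Leaving out 1 array at a time gave p between 0.0031 and 0.69, and the call ended without Ctrl replicate 1, Ctrl replicate 2, MPP replicate 1, Pselt replicate 1, Pselt replicate 3 or Pselt+MPP replicate 2. The number of lists was 3 without MPP replicate 3, 2 without Pselt replicate 2 and 4 without Pselt replicate 3. Across all 4 groups, limma's F test called 55 probe sets, with 2289 at an unadjusted p below 0.05.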

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

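The tests in this part were planned before their results were seen, with some exceptions. Chosen only after the results were seen were the margins for spread in the 2 tests of the cell division lists and the G2/M value beside the first. So were the comparison of single array means and the correlation without the 2 farthest arrays.

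Of 47 gene lists 1 passed the test of whether the peptide altered the MPP effect, the G1/S and DNA replication genes, with a camera adjusted p of 0.043 and a median interaction of 0.15 (adjusted p = 0.96 with an estimated correlation). The p was 0.048 on ranks, 0.16 among probe sets above the median signal and 0.17 with cyclic loess. Leaving out 1 array ended the call without Ctrl replicate 1 (0.24), Ctrl replicate 2 (0.079), MPP replicate 1 (0.69), Pselt replicate 1 (0.052), Pselt replicate 3 (0.38) or Pselt+MPP replicate 2 (0.24). A modification of the toxin's effect on these genes is therefore not established by these arrays.

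Camera placed the G1/S and G2/M lists lower in MPP than in Ctrl and higher in Pselt+MPP than in MPP. But both comparisons share the MPP arrays, which alone pushes their changes in opposite directions. All 4 calls were lost with an estimated correlation (adjusted p = 0.33 and 0.45, then 0.65 and 0.65), those of the rise also with cyclic loess (0.52 and 0.12). The MPP effects without and with Pselt, which share no arrays, had medians of -0.31 and -0.16 for G1/S and -0.31 and -0.2 for G2/M, and their difference passed only for G1/S, with the losses above (adjusted p = 0.76 for G2/M), so a return with Pselt is not established. For G1/S each MPP array mean lay below each Ctrl array mean, which argues against 1 MPP array alone setting the difference. They were 10.63, 10.77 and 10.81 in MPP and 11.08, 11.04 and 11 in Ctrl. At the preset correlation the G1/S call held in 12 of 12 leave-outs (camera adjusted p from 3.7e-09 to 1.7e-05). The mean G1/S change of -0.309 had a weakest value of -0.257 without MPP replicate 1. That lies below the bound of -0.2 by less than its standard error of 0.069, so the planned test did not decide. For the G2/M list the array means do not argue against it either, since MPP replicate 3 (11.74) lay above Ctrl replicates 2 and 3 (11.71 and 11.67). Its mean change of -0.272 had a weakest value of -0.205 (standard error 0.17) without MPP replicate 2. For a drift between arrays that could also move these genes, the G1/S list mean and the first principal component of the other genes, both as deviations from the group mean, had a correlation of 0.19 over 12 arrays (exact permutation p = 0.76, jackknife error 0.5, and -0.15 without the 2 farthest arrays). That correlation lies below the bound of 0.3 set for excluding such a drift, but by less than its error, so the drift and a response of cycling to treatment cannot be told apart for these genes.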

How the results depend on the processing

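Leaving out the 2 farthest arrays and the comparison of MPP effects without the M-field probe sets were chosen after the results were seen, and all other alternatives here were planned. With an unadjusted p below 0.05 and a 2-fold change, counts were 21 for Pselt against Ctrl, 14 for Pselt+MPP against MPP, 63 for the interaction and 94 for Pselt+MPP against Ctrl. Array weights gave 146 for Pselt+MPP against Ctrl (61 of 61 shared), 85 for Pselt+MPP against Pselt (41 of 41 shared) and 123 for the F test. The 2 groups alone gave 25 for Pselt+MPP against Pselt. Without Pselt replicate 3 and MPP replicate 3 the counts were 100 for Pselt+MPP against Ctrl, 27 for Pselt+MPP against Pselt and 88 for the F test. Leaving out each array in turn gave 35 to 69 for MPP against Ctrl, 0 to 1 for Pselt against Ctrl, 32 to 80 for Pselt+MPP against Ctrl, 22 to 37 for Pselt+MPP against Pselt, 44 to 79 for the F test, and 0 for Pselt+MPP against MPP and for the interaction. The correlation of the MPP effects over called probe sets was 0.852 without the M-field ones and 0.954 to 0.984 over the leave-outs, against 0.418 over all probe sets, and that of the Pselt effects over all probe sets was 0.182 to 0.394. Fry's directional test called 2 lists for MPP against Ctrl (camera 6), 12 for Pselt+MPP against Ctrl (13), 4 for Pselt+MPP against Pselt (8), and 0 for Pselt against Ctrl (1), Pselt+MPP against MPP (3) and the interaction (1). Where values moved, the cause was not tested. No paired analysis was possible because the titles number the arrays in 1 series, so that no groups share a replicate number. Normalization from raw scans and filters on detection were not run.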

Other observations

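The tests on the M-field probe sets and on Pselt replicate 3 were chosen only after the results were seen, as was the margin for spread in the test of a shared Pselt response.

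Some stress-related groups not described so far had single members that rose with MPP+. VEGFA, an angiogenic growth factor of the hypoxia response list, rose 2.64-fold for MPP against Ctrl (log2 change 1.4, SE 0.21, adjusted p = 0.0023, limma). It was the only one of 21 members past the threshold over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.97, mean 0.04, median -0.07). The VEGFA call held in 12 of 12 leave-outs. With both treatments against Ctrl, VEGFA passed (limma adjusted p = 0.044), but that call held in only 3 of 12. Its MPP log2 change in the presence of Pselt was 0.97. Among 10 metallothioneins, small metal-binding proteins, MT1F rose 1.87-fold (log2 change 0.9, SE 0.18, adjusted p = 0.048), a call that held in only 2 of 12 leave-outs, those of Ctrl replicate 1 and Pselt replicate 3, with p up to 0.25 in the others. Adjusted over the list alone 4 metallothioneins rose, among them MT1X and MT2A (0.63 each), and 1 fell, while the list did not pass (camera adjusted p = 0.072).

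With both treatments against Ctrl, further lists lay higher: ER chaperones (camera adjusted p = 0.0063), NRF2 targets (0.0085), other antioxidant enzymes (0.014), Parkinson disease genes (0.042), mitophagy genes (0.045), N-glycosylation genes (0.049) and complex I subunits (0.049). With an estimated correlation none of these 7 passed (adjusted p = 0.22, 0.22, 0.22, 0.29, 0.29, 0.22 and 0.77 in that order). With cyclic loess, and also among probe sets above the median signal, all but the NRF2 call were lost, and the NRF2 call was lost with camera on ranks (adjusted p = 0.063). The ER call held in 12 of 12 leave-outs. Without Ctrl replicate 1 the other 6 were lost, and without Pselt+MPP replicate 1 all of these except the antioxidant enzymes. The call of the Parkinson genes was also lost without Ctrl replicate 2, Ctrl replicate 3 or Pselt+MPP replicate 3, that of the mitophagy genes without Ctrl replicate 2 or Pselt+MPP replicate 2, that of the N-glycosylation genes without MPP replicate 3, Pselt replicate 2 or 3, or Pselt+MPP replicate 2 or 3, and that of complex I without Ctrl replicate 2, any MPP array, Pselt replicate 3 or Pselt+MPP replicate 3. The highest p in these leave-outs was 0.12 for NRF2 targets, 0.05 for antioxidant enzymes, 0.076 for Parkinson genes, 0.18 for mitophagy, 0.19 for N-glycosylation and 0.26 for complex I. GPX8, a peroxidase of the ER, rose among the antioxidant enzymes (log2 change 1.17, SE 0.23, adjusted p = 0.037), a call lost with cyclic loess (0.06) and without Ctrl replicate 2 (0.14), Ctrl replicate 3 (0.18), or Pselt+MPP replicate 1 (0.13), 2 (0.2) or 3 (0.079). NQO1 (1.02, SE 0.21), the mitophagy receptor CALCOCO2 (0.69, SE 0.17) and the complex I subunit NDUFA10 (0.95, SE 0.2) passed only when adjusted over the list alone. For Pselt+MPP against Pselt, ferroptosis and iron genes passed (camera adjusted p = 0.0063, adjusted p = 0.11 with an estimated correlation), and the call was lost on ranks (adjusted p = 0.32). Of 18 members 2 rose over all genes and adjusted over the list alone, SLC7A11 and CHAC1, which also belong to the ATF4 list, and the list was not tested without them.

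For the 6 probe sets with M in the chromosome field that fell with MPP+, the 25 next dimmer other probe sets in Ctrl were examined. For each of the 6, 100% of these were brighter in MPP. For 510 other bright probe sets the median was 36% and the 95th percentile 92%. A dimming that follows signal level alone would keep their order. But these 6 were chosen for their fall, and RMA brings the arrays to a common distribution. A lost order was thus nearly given by the choice, and the test cannot decide on such a dimming. If all 10 probe sets with M in that field are mitochondrial transcripts, as the field would have it, an equal loss of all of them is argued against. Their highest and lowest change lay 9.4 apart (standard error 0.45). Over the 9 probe sets before a gap in the numbering, chosen after the values were seen, the Spearman correlation of change and identifier number was -0.933 (exact permutation p = 0.00075), but over all 10, with the one that rose, it was -0.406 (exact permutation p = 0.25). Among named probe sets, on the first 25% of identifiers of each chromosome, numbers followed position with a Spearman correlation above 0.99 on 23 of 24 chromosomes (lowest 0.641). So a candidate explanation, a loss that grows along 1 long precursor transcript, stays open and needs the identity of these probe sets.

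No gene passed for Pselt against Ctrl. An outlying array, Pselt replicate 3, may have hidden changes, but without it 0 genes passed while the toxin comparison against the remaining Pselt arrays called 27. For single genes this argues against hidden changes as large as those of the toxin, but not against smaller ones. Even with 3 arrays per group, limma called only 12.2% of simulated 1.5-fold changes. For lists a hiding of changes by that array stays open, since 12 passed without it and 0 with an estimated correlation. A weak response shared by cells with and without MPP could also stay below the threshold. The correlation of both Pselt effects, 0.304, was reached by 11 of 100 regroupings of the arrays (highest other 0.422), 1 above the bound of 10 for excluding such a response with a spread of 3.1, so it can neither be shown nor excluded here.

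Other splits of the same arrays were counted for each result. For the pairwise comparisons the 10 splits of 6 arrays are too few for a share under 0.05. As many genes as in the real split came from 1 of 10 splits for MPP against Ctrl (53, highest other 0), Pselt+MPP against Ctrl (61, highest other 0) and Pselt+MPP against Pselt (41, highest other 0), and from 10 of 10 for Pselt against Ctrl (0, highest other 1) and Pselt+MPP against MPP (0, highest other 0). For the F test 1 of 100 splits of the 12 arrays, the real one, gave 55 genes and the highest other gave 51. The share of splits that reached the real count was thus under 0.05, by a narrow margin in genes. If the arrays of a group are not separate cultures, which the labels leave open, such splits cannot exclude chance differences between cultures. For the interaction 100 of 100 splits gave as many as the real 0, a count that every split reaches. The highest other, 107, points to a structure of the samples, and the toxin treatment is itself one, since these splits mix treated with untreated arrays; no other structure was tested.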
